A study of Cannabis sativa with 12 samples.

How the data were processed

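Small RNAs from leaves of Cannabis sativa, cultivar Pink Pepper, were sequenced in 12 libraries made from total RNA with a TruSeq small RNA kit. The libraries fall into 4 groups of 3, named in the labels: control (23 °C), cold (5 °C for 168 h), putrescine (a foliar spray of 5 mL at 0.9 mM) and cold with putrescine. Per the labels' protocols, the putrescine-treated plants were kept in a chamber of their own, so putrescine and chamber cannot be told apart, and the temperature of the group given only putrescine is not stated in the sources used here. No label names a sequencing batch.

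The analysis started from 3 kinds of deposited table. For each library the authors deposited values for 193 small RNA names in RPM (reads scaled to a fixed total over those names), made with a quantifier program. For each library the authors also deposited a normalized signal per name, made by dividing the reads by 1 DESeq2 size factor per library. A further table the authors deposited for the whole series lists predicted pairs of small RNA and transcript with a psRNATarget expectation score, in which a lower score marks a closer match and the highest value is 5. Per the submitters' processing notes, cutadapt 4.6 and Bowtie 1.3.1 were used upstream, and DESeq2 and DESeq are named without a version. The genome build and the miRNA annotation are not given in the sources used here.

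Each normalized value was a whole multiple of 1 step per library (100% of values within a tolerance of 1e-06), and these multiples gave back the RPM values, so reads per name and per library were recovered from them. The recovered totals ran from 889344 to 3595046 reads per library. Size factors ran from 0.446 to 2.17, and a median of ratios over the 105 names read in all libraries gave the authors' factors back (ratio 1). A level of 3 reads, used as the limit that a count of 0 allows, equals 1.38 to 6.72 normalized reads depending on the library. This limit covers counting error only, because the reads carry no molecular identifiers here.

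Sequences were taken from the prediction table for 191 of the 193 names and came to 156 distinct sequences. 55 names share their sequence with another name. The reads of such names cannot be told apart, and names with the same sequence and the same reads in all libraries are counted as 1 item where items are given. The tests, the lists and the adjustment ran over names, and 1 name per sequence was tried as an alternative. The names carry no family number, so a family was assigned to 31 names in 19 families where the sequence lay within 2 mismatches of 1 of 33 conserved plant miRNA sequences, over at least 18 nt. Those 33 sequences were written down from general knowledge of plant miRNAs and not taken from a database. No name was that of an animal miRNA. All 13212 transcripts of the prediction table were matched to gene names in a RefSeq table of the Pink Pepper assembly ASM2916894v1, which was used for names only.

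The tests planned before the data were examined were count tests with TMM scaling and a filter on counts. The tables hold normalized values, so the comparisons were instead made with limma (3.58.1, R 4.3.3) on log2(normalized value + 1), with a trend of the spread with the level. The filter was set after the files were seen and before any test was run: a name was tested where at least 3 libraries held 10 normalized reads or more, which kept 118 names (94 items). A fold change is therefore on the log2(value + 1) scale, which understates the change of low names. All 4 groups entered 1 fit, and the comparisons were contrasts of the group means. The averaged comparisons of cold and of putrescine (6 libraries against 6) used an additive model. The p-values were two-sided and adjusted by Benjamini and Hochberg over the 118 names of a comparison, with a threshold of 0.05. 8 comparisons were made.

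The names reported were chosen by a rule written before the data were examined: per comparison every name past the threshold (if 25 or fewer), the 5 smallest p-values where fewer than 5 passed, the 2 members of each list with the smallest p-values, and the 8 most abundant names. 9 lists of miRNA families were fixed at the same time. Lists with at least 3 tested members were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists of a comparison. The share of the variation between libraries that followed a treatment, and the correlation of responses across names, were tested by exact permutation of the labels (400 assignments, two-sided). Library properties were compared by exact permutation of 20 assignments, two-sided. Correlations between comparisons that share libraries were set beside 1000 simulations in which unchanged groups share them. Themes among predicted targets (19, fixed before the data were examined) were tested with Fisher's exact test, two-sided.

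The code was tested on simulated data for the comparison of cold with control, with 118 names, 30 of them changed in each of 50 simulations, and a dispersion of 0.211. It called 15.8% of names changed 2-fold, 71.8% of those changed 4-fold and 94.2% of those changed 8-fold, against 1.16% of unchanged names. With no change at all, 0.123% of names were called. A shifted list was called in 50 of 50 simulations, against 0.571% of lists left unshifted. The simulated names varied independently of each other, and all had the same dispersion. A change in a name that varies more than this would be called less often. In the data the estimated correlation within a list was 0.97 for the phase change list and 0.57 for the auxin list. The rate for unshifted lists therefore does not carry over to the list calls.

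Alternatives planned in advance were total-read scaling, limma-voom on the recovered reads, no filter, a mean of 10 reads or more, a replicate block, only the 2 groups compared, summing by family, leaving out the most abundant family, and leaving out each library in turn. Further alternatives were chosen after the data had been seen: TMM factors computed with code written for this purpose, pseudocounts of 0.5 and 5, 1 name per sequence, a fit without the trend, target themes of the names called in the interaction, and themes from unadjusted p-values with expectations of 3 or less. The count tests planned with edgeR and DESeq2 were not run: the deposited values are normalized, and low values were too few per library to accept the recovered reads as counts. limma-voom was run on the recovered reads in their place. Values were joined and drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.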

Results

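Small RNAs were sequenced from leaves of Cannabis sativa, cultivar Pink Pepper, to follow the response to cold and to putrescine, a small polyamine. There were 4 groups of 3 libraries: control at 23 °C, cold at 5 °C for 168 h, leaves sprayed with 5 mL of 0.9 mM putrescine, and cold with putrescine. The control libraries 1, 2 and 3 held 1226586, 1257633 and 2942804 reads on the 193 small RNA names. The cold libraries held 889344, 1971269 and 1321366 reads, the putrescine libraries 3595046, 2338605 and 3522542, and the libraries of both treatments 3250296, 1590933 and 2468983. Levels below are the authors' normalized reads as mean ± SD with n = 3 per group, and adjusted p-values come from limma on the log2(value + 1) scale over 118 tested names. Nothing in the labels says that the replicates of a group are separate plants, so the p-values measure only the spread between these samples. Putrescine-treated plants were kept in a separate chamber, so every difference between groups with and without putrescine is also one between chambers. Control at 23 °C and cold at 5 °C cannot have shared 1 chamber at 1 time, so a difference in cold may also be one of chamber or time. The temperature of the group given only putrescine is not stated.

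A single small RNA, Cannabis_1 (UCGGACCAGGCUUCAUUCCCC), made up most of every library. Its sequence is that of miR166, a regulator of the HD-ZIP III genes of leaf polarity. It took 94.2 ± 1.56% of the reads in control, 88.6 ± 2.00% in cold, 95.2 ± 0.548% with putrescine and 93.2 ± 4.28% with both. The difference between cold and control was −5.59 percentage points (exact permutation p = 0.1, the smallest that 3 libraries against 3 can give). The shares in cold with and without putrescine gave an exact permutation p of 0.2. The 8 most abundant names together held 98.1% to 99.5% of the reads. Among them were miR168, miR408, miR398, miR396 and miR159 by sequence. Reads of names that share a sequence, miR408 among them, enter the totals and shares once for each name. The reads outside Cannabis_1 ran from 52411 in control 1 to 217404 in control 3, and between 7 and 45 names were listed at 0 in a library.

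The first question was what cold changed in the absence of putrescine. In cold leaves 10 of the 118 names changed against control, of which 8 rose and 2 fell. miR827 (Cannabis_9, UUAGAUGACCAUCAACAAACA), known from other plants for its part in phosphate balance, rose from 87.9 ± 83.1 to 3464 ± 3288, with levels of 438, 2992 and 6962 in the cold libraries (31.0-fold, log2 4.96, SE 1.13, adjusted p = 0.0319). miR168 (Cannabis_6, UCGCUUGGUGCAGGUCGGGAA), which in plants controls the transcript of ARGONAUTE1, rose from 4083 ± 1043 to 12162 ± 1685 (3.03-fold, log2 1.60, SE 0.33, adjusted p = 0.0290). A member of the miR156 family (Cannabis_31, UUGACAGAAGAGAGAGAGCAC), the family that holds back the change from juvenile to adult growth, rose from 76.8 ± 85.2 to 636 ± 372 (10.8-fold, adjusted p = 0.0443). miR164 (Cannabis_27, UGGAGAAGCAGGGCACGUGCA), a regulator of NAC genes of organ boundaries, fell from 183 ± 54.0 to 51.2 ± 11.6 (log2 −1.80, SE 0.44, adjusted p = 0.0321).

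The other 6 names that changed in cold belong to no assigned family. Cannabis_96 (CGACCAUCGGACCUGGGGUG) rose from 78.6 ± 80.1 to 467 ± 146, Cannabis_133 (CCCUGGCUGGAGUGGAUAUCGC) from 183 ± 203 to 846 ± 293, Cannabis_29 (UGAGAUGAUUUAUUGAAUUGCU) from 90.2 ± 69.1 to 310.1 ± 45.0 and Cannabis_45 (UUUUUUCGAAUCCAACAACAUG) from 9.28 ± 2.40 to 53.9 ± 17.1. Their log2 changes were 3.14, 2.90, 2.02 and 2.40. Cannabis_125, for which no sequence was known, rose from 0.472 ± 0.478, under the level of 3 reads, to 16.8 ± 6.55. It rests on 0 to 16 reads per library. The 24-nt Cannabis_155 (ACCGCGACCGCACUGUAAAGAAUU) fell from 40.6 ± 3.67 to 13.3 ± 4.09 (log2 −1.58, adjusted p = 0.0443). For each of the 10 names 3 of 3 cold libraries lay on the called side of the control mean. The choice of these names by the same comparison makes that likely.

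Other abundant miRNAs did not pass. miR408 (Cannabis_3 and Cannabis_4, AUGCACUGCCUCUUCCCUGGC), a copper-associated miRNA, stood at 9914 ± 8263 in control and 40303 ± 7141 in cold (log2 2.61, SE 0.86, adjusted p = 0.0722). miR398 (Cannabis_5, UGUGUUCUCAGGUCGCCCCUG), which targets copper and zinc superoxide dismutases in other plants, stood at 4883 ± 4448 and 10825 ± 5555 (adjusted p = 0.335). At an unadjusted p under 0.05 there were 26 names, and 25 (21.2%, where chance gives 10%) did not overlap between the groups. Of the control and cold libraries, control 2 and cold 1 lay farther from their own group than from the others. Their median distances over the log2 values were 23.1 against 15.6 and 17.3 against 15.5. The number of calls rested on single libraries: it was 0 without control 3, 0 without cold 2, 0 without cold 3, 5 without putrescine 2, 3 without putrescine 3 and 22 without cold 1. It was also 0 in a fit of the 2 groups alone and 20 with no filter. With the miR166 family left out of the scaling 2 names were higher and 13 lower. That scaling moved the median log2 change of all tested names from 0.08 to −0.84, so its split of directions is relative to this shift. The reads it divides by include miR408, counted under 2 names, at the levels given above.

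**Figure D1:**
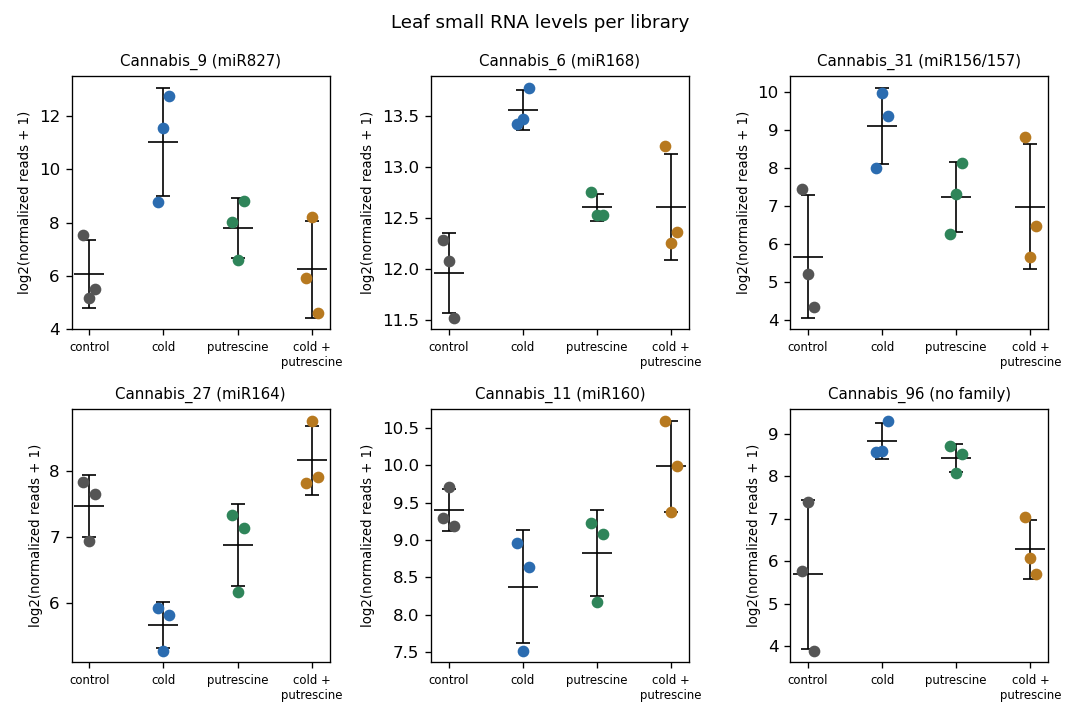
Levels of 6 small RNAs in each of the 12 libraries, as log2(normalized reads + 1) on axes that do not start at 0, by treatment group; points are libraries, horizontal lines are means of 3 libraries and bars are ± 1 SD on that scale. miR827, miR168 and Cannabis_31 of the miR156 family were higher in cold than in control, where miR827 went from 87.9 to 3464 normalized reads, and miR164 was lower, at 51.2 against 183.

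Groups of miRNA families fixed in advance were followed through all comparisons. The phase change list had 3 tested names of 2 sequences, all of the miR156 family. In cold 1 of them rose, 3 passed when adjusted over the list alone, and the list was higher than the other names by camera (adjusted p = 0.0356), but not past the threshold at adjusted p = 0.481 with an estimated correlation. Cannabis_32 and Cannabis_33 (UGACAGAAGAGAGUGAGCAC) of this list stood at 38.6 ± 33.9 in control and 180 ± 73.2 in cold (log2 2.53, adjusted p = 0.0546). The auxin list had 9 tested names of 4 sequences, those of miR160 and miR167, regulators of auxin response factors. In cold none was called and 0 passed when adjusted over the list alone, 8 of the 9 (3 of the 4 sequences) had a negative log2 value, and the list was lower by camera (adjusted p = 0.0356), with adjusted p = 0.481 with an estimated correlation. With putrescine alone against control, the auxin list and the meristem and polarity list (5 names of miR164, miR166 and miR171) were both lower (adjusted p = 0.0158), with adjusted p = 0.511 with an estimated correlation for each, 0 names called in either and 0 when adjusted over the list alone.

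In cold leaves the auxin list was higher with putrescine than without (adjusted p = 0.0213), with 0 names called, 3 passing when adjusted over the list alone and adjusted p = 0.478 with an estimated correlation. Its median log2 value was 0.40, and −0.02 by RPM, a scaling that moved the median of all names in this comparison from −0.07 to −0.42. Under putrescine the auxin list (adjusted p = 0.00781) and the meristem list (adjusted p = 0.0143) were higher in cold than without cold, with 0 names called or passing over the list alone, and with adjusted p = 0.585 for both with an estimated correlation. In the interaction of cold and putrescine the phase change list was lower (adjusted p = 0.0439), and the auxin list (adjusted p = 0.00503) and the meristem list (adjusted p = 0.0415) were higher, each with adjusted p = 0.454 with an estimated correlation. In it 0 of the 3 phase change names were called, 3 of the 9 auxin names were called higher, all of them miR160 of 1 sequence, and 1 of the 5 meristem names was called higher, miR164. When adjusted over the list alone, 3, 3 and 1 names of these lists passed. The 10 list calls fell to 0 with an estimated correlation and to 0 by fry. They were made over names, some of which share a sequence: with 1 name per sequence 8 of the 10 could be tested and 0 were called (smallest adjusted p = 0.113), while the phase change list had too few members. Summed by family only the 3 calls of the meristem list could be tested, and 0 were called (smallest adjusted p = 0.106). By RPM there were also 10, but not the same ones: the meristem list was not called in the interaction or under putrescine, nor the auxin list in cold against control. The phase change list was called instead for putrescine against control, putrescine in the cold and both treatments against control. The list calls numbered 6 without control 2, 5 without cold 1, 5 without cold 2 and 4 without putrescine 2.

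With all libraries the other lists were not called in any comparison. In cold, 0 of the 3 copper-associated names (miR398 and miR408) were called and 2 passed when adjusted over the list alone (list adjusted p = 0.113, and 0.0444 without control 3). Of the 3 nutrient names miR827 alone rose, while miR399 and miR2111 did not pass (list adjusted p = 0.449). The leaf growth list (4 names of miR159, miR319 and miR396) had 0 called and 0 when adjusted over the list alone (adjusted p = 0.734). Of 6 tested names from families that respond to cold in Arabidopsis 0 were called, 2 passed when adjusted over the list alone, both miR408, and the list was at adjusted p = 0.734 with a median log2 value of −0.01 and a mean of 0.70. The small RNA machinery list had 2 tested names, too few for a test, of which miR168 rose in cold and miR162 did not pass. No name of the disease resistance list was tested.

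Putrescine alone was compared with control to ask what the spray changed without cold. limma called 0 names, with 21 at an unadjusted p under 0.05 (17 higher, 4 lower), and limma-voom also called 0, with 21 unadjusted. The smallest adjusted p was 0.190, shared by 13 names, among them Cannabis_96, Cannabis_29 and the trio of Cannabis_49, Cannabis_52 and Cannabis_107. Cannabis_96 stood at 353 ± 77.3 with putrescine and 78.6 ± 80.1 in control (log2 2.75), and Cannabis_29 at 217 ± 20.9 and 90.2 ± 69.1 (log2 1.52). The groups did not overlap for 29 names (24.6%, where chance gives 10%). Without control 2 there were 7 calls.

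Log2 changes in cold and in putrescine, each against control, were correlated across the 118 names (r = 0.76, rho = 0.70), which are not independent replicates. The control libraries are shared, and unchanged groups that share them gave a median r of 0.54 in simulation (95% range −0.17 to 0.91). The covariance was 1.17 against a simulated 0.406, a difference of 0.768, and 7% of simulations were as high. With 3 controls they could not be split so that each part kept 2, so part of the excess may come from the shared libraries.

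In cold leaves, putrescine changed 3 names. miR164 (Cannabis_27) rose from 51.2 ± 11.6 without to 299 ± 117 with putrescine (5.59-fold, log2 2.48, SE 0.44, adjusted p = 0.0160). miR827 (Cannabis_9) fell from 3464 ± 3288 to 126 ± 146 (log2 −4.79, SE 1.13, adjusted p = 0.0496), and Cannabis_125 fell from 16.8 ± 6.55 to 1.12 ± 1.24 (log2 −3.19, adjusted p = 0.0324). All 3 moved the opposite way in cold against control, a comparison that shares the cold libraries with this one. Across names the log2 changes of both comparisons had r = −0.83, within the simulated 95% range of −0.89 to 0.30 (median −0.51) for unchanged groups that share libraries, and 6.7% of simulations were as low. Their covariance was −1.57 against a simulated median of −0.382, and 2.2% of simulations were as low.

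Of the names that did not pass in this comparison, miR160 (Cannabis_11, with Cannabis_12 and Cannabis_90, UGCCUGGCUCCCUGUAUGCCA) stood at 359 ± 160 without and 1078 ± 446 with putrescine (log2 1.62, adjusted p = 0.0689), and miR168 at 12162 ± 1685 and 6531 ± 2536 (log2 −0.95, adjusted p = 0.117). There were 27 names at an unadjusted p under 0.05, and 28 (23.7%, where chance gives 10%) did not overlap between the groups. The count of 3 became 0 without cold 2, 0 without cold 3, 0 without both-treatment library 3, and 1 without both-treatment library 2 or any 1 of the putrescine libraries 1, 2 and 3. It became 15 without control 2, 5 without control 3, 12 without cold 1, 6 with no filter, 1 with a pseudocount of 0.5 and 7 with the miR166 family left out.

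Among putrescine-treated plants, limma called 0 names between cold and no cold, with 16 at an unadjusted p under 0.05 (6 higher, 10 lower), and limma-voom called 0, with 14 unadjusted. The smallest adjusted p was 0.185, for Cannabis_15 (UGCCAAGAGGAGUUGCCCUGU), at 221 ± 116 in cold and 670.2 ± 114 without (log2 −1.70). Cannabis_140 (AGAAGUUUGGUAUUGCUCCUUUA), identical in sequence to Cannabis_141 and Cannabis_147, stood at 42.3 ± 18.5 in cold and 220.4 ± 163 without (log2 −2.22, adjusted p = 0.251). The groups did not overlap for 42 names (35.6%, where chance gives 10%). Without both-treatment library 2 there was 1 call.

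Plants given both treatments were also set against control. limma called 0 names, with 4 at an unadjusted p under 0.05 (1 higher, 3 lower) and a smallest adjusted p of 0.721, and limma-voom called 0, with 3 unadjusted. Cannabis_139 stood at 7125 ± 1749 with both treatments and 2901 ± 1569 in control (log2 1.39, adjusted p = 0.721). The level of miR827 was 126 ± 146 with both and 87.9 ± 83.1 in control, and that of miR164 299 ± 117 and 183 ± 54.0. The groups did not overlap for 9 names (7.63%, where chance gives 10%).

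The interaction asked whether the response to cold differed with putrescine. It did for 17 names in 15 items, of which 13 had a lower and 4 a higher response with putrescine. With 1 name per sequence there were 13 calls, 11 lower and 2 higher. miR827 had a log2 change in cold of 4.96 without and −1.56 with putrescine (interaction −6.52, SE 1.60, adjusted p = 0.0309). miR164 had −1.80 without and 1.28 with putrescine (interaction 3.08, SE 0.63, adjusted p = 0.0161), and miR160 (Cannabis_11) −1.03 and 1.17 (interaction 2.20, adjusted p = 0.0483). miR168 had 1.60 without and 0.00165 with putrescine (interaction −1.60, SE 0.47, adjusted p = 0.0483). It was the only one of the 17 whose 2 responses did not have opposite signs. The choice of the 17 by the interaction makes opposite signs likely. Cannabis_96 (interaction −5.31, SE 1.03) and Cannabis_125 (interaction −5.21, SE 0.95) had the smallest adjusted p, 0.0157 each. The means of Cannabis_125 in control (0.472) and with both treatments (1.12) lay under the level of 3 reads, so the size of its value depends on the pseudocount, and it ranged from −6.27 to −2.66 over the alternatives. Cannabis_96 was at 467 ± 146 in cold and 353 ± 77.3 with putrescine, against 78.6 ± 80.1 in control and 83.1 ± 42.7 with both.

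**Figure D2:**
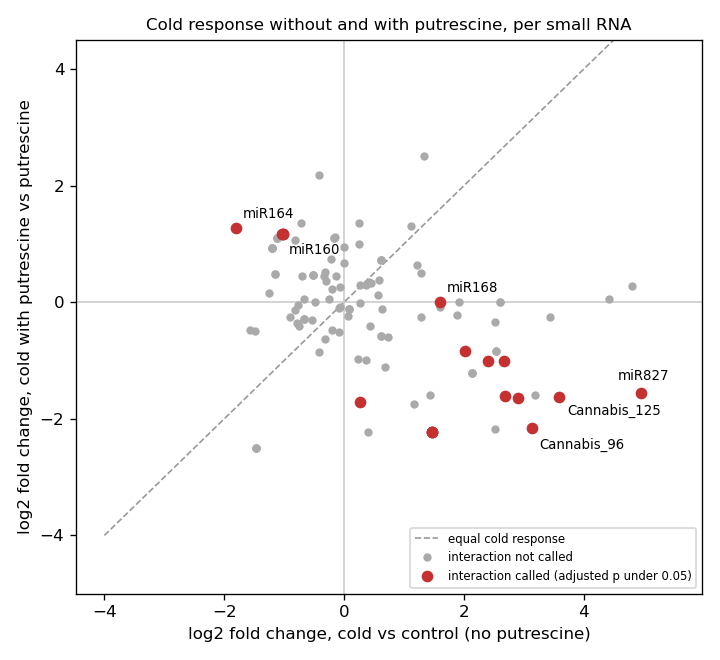
Log2 fold change in cold without putrescine (horizontal axis) against that with putrescine (vertical axis) for each of the 118 tested small RNAs; red points are the 17 names called in the interaction and the dashed line marks equal responses. Called points lie away from the line, which follows from their choice by the interaction test, with miR827 at 4.96 and −1.56 and miR164 at −1.80 and 1.28.

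8 of the 17 names were also called in cold against control, a comparison that forms part of the interaction. 6 of the 17 have a family, those of miR827, miR168, miR164 and miR160. There were 26 names at an unadjusted p under 0.05 (4 higher, 22 lower), and limma-voom called 23, among them all 17. The number called was 9 without control 1, 4 without control 3, 28 without cold 1, 10 without cold 2, 3 without cold 3, and 3, 4 and 3 without putrescine 1, 2 and 3. It was 3 without both-treatment library 3, 5 by RPM, 8 with the miR166 family left out (5 higher, 3 lower) and 10 with a pseudocount of 0.5. Leaving out that family moved the median interaction value of all tested names from −0.07 to 0.62. Cannabis_96 passed in 24 of 24 alternatives, Cannabis_125 in 23 of 23 and miR164 in 23 of 24, whereas miR827 passed in 18 of 24 and miR168 and miR160 in only 8 of 24 each.

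Averaged over both backgrounds, neither treatment had a called name. Opposite responses in the 2 backgrounds cancel in these averages and add to the remaining spread, so 0 calls do not show that neither treatment acted. For cold limma called 0, with 7 at an unadjusted p under 0.05 (3 higher, 4 lower) and a smallest adjusted p of 0.394, and limma-voom called 0, with 6 unadjusted. Cannabis_155 had the smallest p, with a log2 value of −1.03. For putrescine limma called 0, with 2 unadjusted (1 higher, 1 lower) and a smallest adjusted p of 0.629, and limma-voom called 0, with 2 unadjusted. Without control 2 there were 3 calls for cold. Cold accounted for 9.75% of the variation between libraries (permutation p = 0.395) and putrescine for 4.96% (permutation p = 0.855). Each of the 400 assignments gives the same share as its mirror image, so fewer than 400 are distinct.

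Responses were also correlated across names between comparisons that share no library. The response to cold without putrescine against that with it had r = −0.39 (exact permutation p = 0.12) and rho = −0.41 (exact permutation p = 0.09). The response to putrescine without cold against that in the cold had r = −0.62 (exact permutation p = 0.03) and rho = −0.60 (exact permutation p = 0.03). The latter was not past the threshold without control 2 (r = −0.46, p = 0.1 by permutation), cold 1 (−0.58, p = 0.07), cold 3 (−0.59, p = 0.07), both-treatment library 2 (−0.56, p = 0.07) or both-treatment library 3 (−0.58, p = 0.05). Both are correlations across names, and the test permuted the libraries.

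The authors' deposited prediction lists 22559 pairs of a small RNA and a transcript, and no transcript was measured here. For miR168 the closest match was the transcript of argonaute 1 (LOC115714148, positions 708 to 728, expectation 2.5), and for miR827 that of an SPX domain-containing membrane protein (LOC115717117, positions 461 to 481, expectation 1). miR164 matched the NAC gene transcript LOC115697141, a homolog of CUC2, at positions 917 to 937. miR160 matched auxin response factor transcripts, among them LOC115718756 at positions 1413 to 1433 (expectation 0). Themes among predicted targets could not be tested for the averaged comparisons, which called 0 names. With names at an unadjusted p under 0.05 in their place, Fisher's exact test called 0 of 19 themes over 116 names with predictions. Of the interaction calls, 6 of 16 had a predicted auxin response factor target, against 13 of 100 other names (Fisher's exact p = 0.0245, adjusted p = 0.465 over the 19 themes).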

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

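The tests of depth, scaling and other splits of the libraries given here were set down before their results were seen, but after the interaction calls were known. 17 names stood out because their response to cold differed with putrescine by the interaction test itself. The log2 response with minus without putrescine was −6.52 for Cannabis_9 (miR827), −5.31 for Cannabis_96, −5.21 for Cannabis_125, −4.55 for Cannabis_133 and −4.29 for Cannabis_188. It was −3.70 for Cannabis_140, −3.70 for Cannabis_141 and −3.70 for Cannabis_147, which share a sequence, −3.68 for Cannabis_150, −3.41 for Cannabis_45, −2.86 for Cannabis_29, −1.97 for Cannabis_15 and −1.60 for Cannabis_6 (miR168). It was 3.08 for Cannabis_27 (miR164) and 2.20, 2.19 and 2.19 for Cannabis_11, Cannabis_12 and Cannabis_90, the names of 1 miR160 sequence.

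Library depth was tested only through the reads outside Cannabis_1. With log2 of these reads as a covariate, the 17 interaction values had a median ratio of 1.00 to those without it and a lowest of 0.903. 11 of the 17 stayed past the threshold, and the median standard error grew by a ratio of 1.09. The reads outside Cannabis_1 need not follow the library total (52411 of 1226586 in control 1, 114694 of 889344 in cold 1). They also include miR168, itself among the 17, so this test does not decide on depth. The authors' scaling is argued against as the whole cause, since under 3 other scalings all 17 kept their sign and the smallest median ratio was 0.841. That ratio came without the most abundant family, where the lowest ratio was 0.537, the standard error grew by a ratio of 1.13 and only 7 of the 17 passed. By RPM only 3 of the 17 passed, where the standard error grew by a ratio of 1.35 and the values had a median ratio of 0.959 and a lowest of 0.772. Of 100 splits of the 12 libraries into 4 groups, 1 gave as many calls as the real one, the real one itself (17, highest other 5). Chance is therefore argued against for the count, but not excluded. The splits break up every treatment effect, so they do not test the interaction alone. They were set down after the interaction calls were known, with no adjustment for that, and treat the libraries as independent samples, which the labels do not state. Leaving out single libraries gave 3 to 28 calls. What also stays open is an effect of both treatments in the plants, a hypothesis behind the 17 names. Every putrescine library came from the separate chamber. A difference between chambers that is the same with and without cold cancels in the interaction. An effect of both treatments cannot be told apart from a chamber difference that changes with cold. Nor can it be told apart from an unlike temperature of the group given only putrescine, which is not stated. Plants that differ genetically between groups, a candidate raised below for Cannabis_21 and Cannabis_108, also stay open. The libraries without these names were control 1, control 3, putrescine 3 and both-treatment library 1, and none was a cold library.

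For the comparisons of 3 libraries against 3 the 10 splits are too few for a share under 0.05. Cold against control called 10 names (highest other split 0) and was the 1 split of 10 with as many, and putrescine in the cold called 3 (highest other 1), also 1 of 10. Putrescine against control, cold under putrescine and both treatments against control called 0, so 10 of 10 splits gave as many (highest others 2, 1 and 2). For the averaged comparisons, with 0 calls, 100 of 100 splits gave as many. The highest other for cold was 14, for the split that sets cold and putrescine libraries against control and both-treatment libraries. That split is the interaction again and adds no separate evidence for it. The highest other for putrescine was 7, for a split that crosses the treatments. It sets control 2, cold 1, putrescine 1, putrescine 2 and both-treatment libraries 2 and 3 against the rest. The 4 libraries without Cannabis_21 and Cannabis_108, described below, were all among the rest.

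For the list calls, cold against control had 2 (3 of 10 splits as many, highest other 3), putrescine against control 2 (4 of 10, highest other 4), putrescine in the cold 1 (5 of 10, highest other 3) and cold under putrescine 2 (2 of 10, highest other 2), where 10 splits are too few. The interaction had 3 list calls, and 4 of 100 splits gave as many (highest other 3). With an estimated correlation all 3 were lost (adjusted p = 0.454 each), so chance was not excluded for these list calls.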

How the results depend on the processing

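The TMM scaling, pseudocounts of 0.5 and 5, 1 name per sequence and the fit without a trend were chosen after the data had been seen; the other settings were planned. The log2 values of the 30 named calls kept their sign under every setting run. Of these calls 18 lost the threshold by RPM, 16 without the most abundant family, 9 with a pseudocount of 0.5, 6 with no filter, 6 without a trend, 3 with TMM, 3 when summed by family and 1 by limma-voom, and 12 of 13 did with only the 2 groups compared. For cold against control the 10 calls became 20 with no filter and 0 with only the 2 groups compared (fewer samples), and leaving out each library gave 0 to 22. Putrescine against control (0) ranged from 0 to 7 over left-out libraries, cold under putrescine (0) from 0 to 1, and cold over both backgrounds (0) from 0 to 3. Putrescine in the cold (3) became 6 with no filter, 7 without the most abundant family and 1 with a pseudocount of 0.5, and ranged from 0 to 15 over left-out libraries. The interaction (17) became 5 by RPM, 8 without the most abundant family and 10 with a pseudocount of 0.5, and ranged from 3 to 28 over left-out libraries. The list calls (10) became 0 with an estimated correlation, 0 by fry, 0 when summed by family (7 had too few members to test) and 0 with 1 name per sequence (2 had too few), and ranged from 4 to 11 over left-out libraries. The correlation of the putrescine responses (−0.62) ranged from −0.66 to −0.46 over left-out libraries. For these changes the cause was not tested. Both treatments against control and putrescine over both temperatures stayed at 0 calls under every setting run.

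With the replicate number as a replicate block, cold against control had 0 calls (27 unadjusted), putrescine in the cold 1 and the interaction 14, and the correlation of the putrescine responses was −0.62 with a permutation p of 0.11. The numbers do not pair the samples: of 18 pairs with the same number 5 had a correlation of deviations over 0.1 (range −0.64 to 0.52), and 2 of 12 libraries correlated best with their own number. Of the 30 named calls 15 lost the threshold under it. The block changed no other call count by over 1.5 times.

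Scaling moved the split of higher and lower calls. Cold against control had 8 higher and 2 lower, against 12 and 0 by RPM and 2 and 13 without the most abundant family. Putrescine in the cold had 1 and 2, against 0 and 2 by RPM and 5 and 2 without that family. The interaction had 4 and 13, against 1 and 16 with TMM, 0 and 5 by RPM and 5 and 3 without that family. Without the family the median log2 change of all tested names went from 0.08 to −0.84 in cold against control and from −0.07 to 0.62 in the interaction, and by RPM from 0.10 to −0.35 in putrescine against control. Depth limits names with few reads: Cannabis_125 rests on 0 to 16 reads per library, Cannabis_150 on 0 to 31 and Cannabis_188 on 0 to 14. Not run were the count tests with edgeR and DESeq2 (too few low values to accept the recovered reads as counts; limma-voom was run on them), the sum over precursors (1 entry per name) and target themes for the averaged comparisons (0 calls).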

Other observations

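The tests of the all-or-none pair, of shared control libraries and of the share of Cannabis_1 were chosen only after the values were seen. 2 of the 193 names were all or none: Cannabis_21 (UUUCGUCGAUGUGGGAUUUCUUUC) and Cannabis_108 (AAGAAAUCCCACAUCGACGAAACA). The search asked for at least 2 libraries at 0 and at least 10 reads in every other library. Both are 24 nt long and pair with each other without mismatch over 22 nt, leaving 2 nt unpaired at each 3′ end, the shape of a duplex released by a Dicer enzyme. In 8 libraries Cannabis_21 stood between 155.7 and 659 normalized reads and Cannabis_108 between 78.6 and 190.2, with 1.53 to 3.47 reads of the former for each read of the latter. Both were at 0 in control 1, control 3, putrescine 3 and both-treatment library 1. The closest predicted target of Cannabis_21 is the transcript of FAMA (LOC115722405, expectation 1), a transcription factor of stomatal guard cells.

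The treatments cannot be the whole cause of this pattern, since 3 of the 4 groups held libraries of both kinds. Nor can depth: at the lowest level of the other libraries, each of the 4 libraries at 0 would have held at least 69.5 reads of Cannabis_21, and the limit that a count of 0 allows there is 1.38 to 6.72 normalized reads. A candidate explanation is that the plants differed at the locus, by its loss or by a sequence variant that kept reads from being counted, so that presence follows the plant in the 4 libraries at 0. No genotype was used here, and this explanation stays open. If it holds, libraries of 1 group came from genetically different plants, and part of the spread within groups may be of that kind. Deviations from the group means correlated between control 1 and putrescine 3 (r = 0.57), control 1 and both-treatment library 1 (0.52), and putrescine 3 and both-treatment library 1 (0.64). Control 3 did not follow putrescine 3 (0.06) or both-treatment library 1 (−0.02), so these values do not decide.

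The 24-nt names, a length typical of small RNAs that guide DNA methylation in plants and not of most miRNAs, were tested as a class against the hypothesis that they respond to cold together. In cold against control the 38 tested names (28 distinct sequences) had a median log2 change of −0.58, against 0.50 for the other 80 names. By camera with the preset correlation the adjusted p was 7.15e-05 over 8 comparisons, and with an estimated correlation it was 0.241. The bound set in advance, an adjusted p of 0.05 or more, was met, but it was badly chosen, because a p that misses the threshold excludes nothing, and the question stays open. Over both backgrounds the medians were −0.27 and 0.33, with adjusted p = 0.128 at an estimated correlation. Among the calls for cold against control were 1 of the 38 and 9 of the 80 others (Fisher's exact p = 0.164). Among the interaction calls were 0 of the 38 and 17 of the 80 (Fisher's exact p = 0.00126). This was the smallest of 8 comparisons, not adjusted for them, over names of which some share a sequence.

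Changes in cold and in putrescine, each against control, went the same way for 78.8% of names, against 67.8% in simulations of unchanged groups that share the control libraries. The covariance of both sets of changes was as high in 7% of those simulations, so the shared control libraries could account for it. The lower share of Cannabis_1 in cold libraries was set against depth: within groups the share correlated with log2 library total at r = 0.39 (exact permutation p = 0.286) and rho = 0.34 (exact permutation p = 0.362), and at r = 0.61 without control 3 and cold 1. miR408 enters each library total under 2 names with the same reads, and its mean level was higher in cold, which lowers the share of Cannabis_1. How much of the lower share this makes up was not tested, and these 12 libraries do not decide between depth and cold.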
